A study of Oryza sativa Japonica Group with 21 samples.

How the data were processed

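Polyadenylated RNA from roots of rice cultivar Nipponbare was sequenced as 76-cycle single reads on an Illumina Genome Analyzer II, per the labels. The 21 libraries fall into 8 groups of 2 or 3, and each library is a pool of tissue from 6 plants, per the labels. Plants received 250 Meloidogyne graminicola or 400 Hirschmanniella oryzae nematodes, or a mock inoculation, and were sampled after 3 and 7 days.

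The deposited table holds a whole-number read count per gene model or transcribed region. TopHat, Bowtie, Cufflinks and SAMtools are named without versions in the submitters' processing notes. The genome build, the annotation release, the counting tool and the treatment of reads that map to several loci are not given in the sources used here. Of the 66341 features, 46599 carry a locus name in the form of the Rice Genome Annotation Project, 8290 are unannotated regions and 11119 have a name with an added suffix whose meaning is not given in the sources used here. Totals of the deposited counts ran from 1530194 to 4739946 per library with a median of 3046233. At that depth a gene with no count in a group is known only to lie below a floor, set here at 3 counts over the group. Intervals and floors cover counting error only, from counts pooled over the libraries of a group. They leave out the spread between libraries, and they take reads as independent molecules, which reads copied by PCR are not.

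Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Features were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 23927, of which 2480 are unannotated regions. Library sizes were scaled with TMM factors, which ran from 0.477 to 1.45. A quasi-likelihood negative binomial model with a mean for each of the 8 groups was fitted to all 21 libraries, with robust shrinkage, so that groups of 2 or 3 share an estimate of spread. The common biological coefficient of variation was 0.636. P-values come from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over all features tested, with a threshold of 0.05. Fold changes are given on the log2 scale with a standard error (SE). Levels are CPM, counts scaled to a common size by the scaled library size and multiplied by 1e+06, computed here from the deposited counts and given as mean ± SD over libraries. Comparisons were galls against mock root tips and Hirschmanniella-infected roots against mock roots at each day, the change of each response between days, the difference between both responses at each day, and mock root tips against mock roots over both days. The difference between both responses also compares tissues, since galls were set against root tips and infected roots against roots without tips.

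The table pairs no locus with a gene symbol. Before the data were examined, 165 gene symbols were written beside their loci from general knowledge of rice, in 18 lists of hormone pathways, defence, photosynthesis, sugars, cell walls, cell types and nutrient uptake. All 165 loci were in the table, by the locus name or, where that was absent, by the locus name with the added suffix. A reference list of rice genes (assembly ASM3414082v1), which holds symbols but no such locus names, placed 117 of the symbols on the chromosome that the locus name gives, lacked 45 and placed 3 on another chromosome. Those 3 were left out, which left 162. Of these, 51 stood under the suffixed name, among them GA20ox1, CATA, YSL15, IRT1, CAB2R and KNOLLE. They are given here by the locus name alone. Of the symbols with a single reference gene on the same chromosome, 113 of 113 stood in the same order there as by locus number. The pairs that the reference lacks were not checked further, so each gene is given with its locus. A further 22 lists defined by words in gene descriptions could not be used, since no descriptions came with the loci. No list member had another feature with near-identical counts (within 10% or 3 counts in every library), but members of gene families such as the light-harvesting, phenylalanine ammonia-lyase and response regulator genes may still share reads.

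The rule for named genes took, from each list with at least 1 member past the threshold, up to 4 members with the smallest p. The text gives values for a part of these genes, and the tables hold the others. A part of the rule that took genes by description could not be applied. A few further list members, and at most 4 loci outside the lists, are named where the text says that they were chosen after their values were seen. Lists with at least 3 tested members, 17 of the 18, were tested with camera at a preset correlation of 0.01, again with the correlation estimated for each list, and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. List p-values are adjusted over the 17 lists of a comparison. Counts of members past the threshold are given over all genes and adjusted over the list alone for the lists described, and the tables hold the others.

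The steps were tested on simulated counts drawn from the fitted means, spreads and library sizes, with 200 genes changed by known folds, 50 at each of 4 sizes. Of the genes changed 16-fold, the test recovered 46% for galls at day 3, 60% for galls at day 7, 50% for Hirschmanniella roots at day 3 and 20% for those at day 7. Of the genes changed 8-fold it recovered 32%, 8%, 16% and 2% in the same order, and of those changed 4-fold 0%, 0%, 6% and 0%. Unchanged genes made up 2 of 42, 1 of 35, 1 of 37 and 4 of 15 calls. Changed genes were few and drawn at random from all 23927 features tested. The adjusted threshold was therefore stricter than in comparisons with many real calls, such as day 7 galls with 1938. The shares recovered are thus no estimate of power in such a comparison. A list of 20 genes lowered 4-fold gave camera p-values from 5.47e-23 to 1.35e-11 in the same 4 comparisons. Simulated genes were drawn independently of each other, so these p-values do not carry over to lists whose members correlate. The estimated correlation was 0.565 for the phytoalexin list between mock root tips and mock roots. Replicates correlated at r = 0.750 to 0.857 across genes on the log2 CPM scale, where genes are not independent replicates. Replicate numbers were not treated as pairs: of 48 same-numbered pairs of libraries, 0 deviated from their group means with a correlation over 0.1.

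Alternatives tried were other scaling factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, fits on fewer groups, the replicate number as a block and leaving out each library in turn. Fits without the 2 loci with the highest counts, with the share of counts at these loci as a covariate, and without the day 3 galls were added after seeing the data.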

Results

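Rice roots were sampled 3 and 7 days after inoculation with 1 of 2 plant-parasitic nematodes. Meloidogyne graminicola is a root-knot nematode whose juveniles settle behind the root tip and induce galls that hold enlarged feeding cells. Hirschmanniella oryzae is a migratory nematode that moves through the root cortex and feeds on the cells along its way. Galls were set against root tips of mock-inoculated plants, with 3 libraries in each of these groups at each day. Whole roots without tips were set against the same tissue of mock plants, with 3 infected and 2 mock libraries at day 3 and 2 of each at day 7. Total counts per library ran from 1530194 to 4739946. The loci LOC_Os09g01000 and LOC_Os09g00999 together took between 0.333% and 65.7% of a library's counts, at most 4.01% in 10 libraries and at least 11.2% in the other 11. Without these loci, 1054883 to 4380467 counts were left per library.

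**Figure D1:**
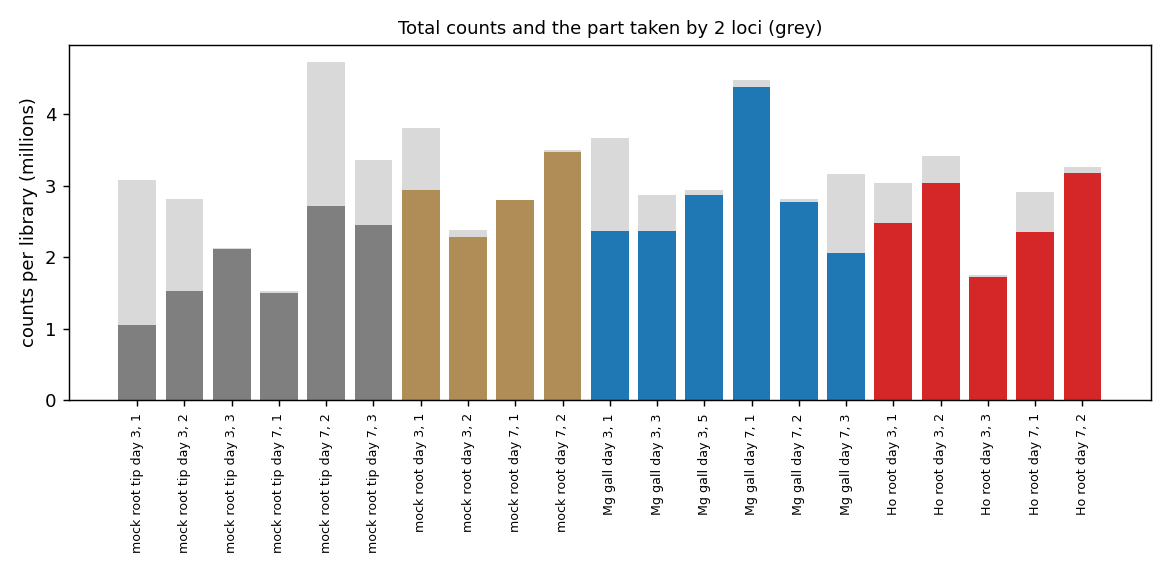
Total counts per library, with the part at LOC_Os09g01000 and LOC_Os09g00999 in grey above the part at all other features, coloured by mock root tip (dark grey), mock root (brown), Meloidogyne gall (blue, Mg) and Hirschmanniella root (red, Ho). The share at these loci ranged from 0.333% to 65.7% and differed among libraries of the same group.

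Which genes change as a gall forms was asked by setting galls against the root tips of mock plants. Young galls at day 3 carried far more transcript of 3 list genes with roles in hormone synthesis, sugar transport and hydrogen peroxide removal than mock root tips. GA20ox1 (LOC_Os03g63970), a gibberellin 20-oxidase, rose 26.3-fold, from 0.817 ± 0.819 to 23.4 ± 7.69 CPM (log2 fold change 4.72 ± 0.80 SE, edgeR adjusted p = 0.00843, n = 3 and 3). CATA (LOC_Os02g02400), a catalase, rose 14.7-fold, from 106 ± 32.0 to 1555 ± 878 CPM (3.88 ± 0.45, adjusted p = 3.97e-04 by edgeR). SWEET4 (LOC_Os02g19820), a sugar transporter, rose 20.3-fold (4.34 ± 0.99, edgeR adjusted p = 0.0390). Another member of that transporter family, SWEET12 (LOC_Os03g22590), fell from 66 counts over the 3 root tip libraries to 0 over the 3 gall libraries, at least 34.3-fold lower (edgeR adjusted p = 0.0194). All gall libraries lay above all root tip libraries for GA20ox1, CATA and SWEET4, and below them for SWEET12.

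Iron uptake genes were lower as a group in day 3 galls. YSL15 (LOC_Os02g43410), a transporter of iron bound to phytosiderophore, fell 12.1-fold, from 31.9 ± 19.7 to 2.67 ± 2.03 CPM (-3.59 ± 0.71, edgeR adjusted p = 0.0202). The iron transporter gene IRT1 (LOC_Os03g46470) fell 8.48-fold, from 46.3 ± 14.4 to 5.38 ± 1.86 CPM (-3.08 ± 0.63, edgeR adjusted p = 0.0222). In all, 2 of the 5 members fell and 3 did so adjusted over the list alone, the third being NAS1 (LOC_Os03g19427), a nicotianamine synthase at -2.74 ± 0.74. The list's median log2 fold change was -2.74 (camera adjusted p = 3.81e-05, and adjusted p = 0.0347 with an estimated correlation).

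Genes of the oxidative burst and its scavenging were higher as a group at day 3, with a median of 0.97 and 6 of 7 members above 0 (camera adjusted p = 4.65e-04, and adjusted p = 0.0325 with an estimated correlation). CATA alone rose over all genes, and a further catalase gene, CATB (LOC_Os06g51150), at 1.93 ± 0.56, passed when adjusted over the list alone. The defence gene PR1a (LOC_Os07g03710), a pathogenesis-related protein gene induced by salicylate, rose 12.2-fold (3.61 ± 0.87, edgeR adjusted p = 0.0479), the 1 of 10 tested members of its list to do so over all genes and adjusted over the list alone. Adjusted over the list alone, 3 further genes passed at smaller size: SUS1 (LOC_Os03g28330), a sucrose synthase, at 1.12 ± 0.29 (edgeR adjusted p = 0.0595 over all genes), the gibberellin response repressor SLR1 (LOC_Os03g49990) at -1.20 ± 0.44, and GA3ox2 (LOC_Os01g08220), a gibberellin 3-oxidase, at least 4.06-fold higher with 19 counts in galls and 0 in tips. The phytoalexin list had a median of 2.57 without passing (camera adjusted p = 0.190). It was 1.57 with genes at 0 counts in 1 group placed at their bound. For this, 3 of 12 members at or below the floor in both groups were left out. The photosynthesis list had a median of 0.11 (camera adjusted p = 0.715). It was 0.03 when handled the same way, with 9 of 25 members at or below the floor in both groups left out. Those 9 have no measured fold at day 3. The other 13 lists also did not pass (camera adjusted p from 0.190 to 0.983). In them 1 of 7 gibberellin and 2 of 15 sugar genes passed over all genes against 3 and 3 adjusted over the list alone. A further 2 of 6 endodermis, exodermis and root hair genes and 1 of 5 ethylene genes were lower adjusted over the list alone. The gibberellin list had a median of -0.33 and a mean of 1.20.

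Over all features tested, 278 differed between day 3 galls and root tips, 144 higher and 134 lower. Over all 23927 features, called or not, the 6 libraries separated completely by group in 4079, where chance gives 10%. Among the genes named, GA20ox1, CATA and YSL15 kept an adjusted p under 0.05 whichever of the 6 libraries was left out. SWEET12 and IRT1 reached 0.0555 and 0.0838 without gall replicate 3. SWEET4 reached 0.120 and 0.0828 without mock root tip replicates 3 and 1 and 0.0690 and 0.0622 without gall replicates 3 and 5. PR1a reached 0.110, 0.129 and 0.0931 without mock root tip replicates 1, 2 and 3 and 0.0609 and 0.163 without gall replicates 3 and 5. Day 3 gall replicates are numbered 1, 3 and 5 in the deposited table. The number of genes fell to 80 without gall replicate 3, to 85 and 121 without mock root tip replicates 3 and 2, and to 0 when the fit held the 6 libraries alone, with adjusted p from 0.106 to 0.222 for the 7 list genes. It was 364 without gall replicate 1. DESeq2 and a fit without a filter also called more, as given with the processing.

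At day 7, when galls were older, the same question was asked. Photosynthesis genes were then higher as a list in galls than in root tips. PSBO (LOC_Os01g31690), a subunit of the oxygen-evolving complex, rose 50.7-fold, from 0.693 ± 1.20 to 39.8 ± 18.2 CPM (5.67 ± 1.05 SE, edgeR adjusted p = 0.00429, n = 3 and 3). CAB2R (LOC_Os01g41710), a light-harvesting chlorophyll-binding protein gene, rose 36.1-fold, from 9 to 414 counts over the 3 libraries, or 44.4 ± 47.3 CPM in galls (5.17 ± 0.92, edgeR adjusted p = 0.00394). LHCA1 (LOC_Os06g21590) went from 0 to 128 counts, at least 29.7-fold higher, and LHCB6 (LOC_Os04g38410) from 2 to 158 counts, a ratio of 55.0 with a 95% counting interval of 15.0 to 458. Of the 25 tested members 9 rose and 0 fell, and 11 rose adjusted over the list alone. The median log2 fold change was 2.33 (camera adjusted p = 6.63e-09, and adjusted p = 0.0289 with an estimated correlation). It was 2.40 with genes at 0 counts in 1 group placed at their bound and 1 member at or below the floor in both groups left out. The other 5 that rose, named after their values were seen, were CAB1R (LOC_Os09g17740) at 2.74 ± 0.85, PSBQ (LOC_Os07g36080) at 2.53 ± 0.68, LHCA4 (LOC_Os08g33820) with a count ratio of 34.1 (9.19 to 285), LHCA3 (LOC_Os02g10390) at least 12.1-fold and PORA (LOC_Os04g58200) at least 9.74-fold higher. These levels stayed far below those of mock roots, where CAB2R stood at 555 ± 275 CPM at day 7.

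Genes of dividing cells fell together in day 7 galls. KNOLLE (LOC_Os03g52650), a syntaxin needed for cell plate formation, fell 6.07-fold, from 141 ± 118 to 23.3 ± 6.74 CPM (-2.60 ± 0.57, edgeR adjusted p = 0.0117). PCNA (LOC_Os02g56130), the sliding clamp of DNA replication, fell 5.58-fold (-2.48 ± 0.71), and the mitotic kinase gene CDKB2-1 (LOC_Os08g40170) fell 3.67-fold (-1.88 ± 0.52), with edgeR adjusted p of 0.0359 and 0.0310. All 6 members were lower in every gall library than in every root tip library. Of these 3 fell over all genes and 6 adjusted over the list alone (median -2.00, camera adjusted p = 4.56e-05, and adjusted p = 0.0289 with an estimated correlation). QHB (LOC_Os01g63510), a homeobox gene of the quiescent centre, fell from 37 to 3 counts (ratio 0.0564, interval 0.0111 to 0.178), the 1 of 4 stem cell niche genes to change. CASP1 (LOC_Os04g58760), a Casparian strip protein gene, fell at -2.40 ± 0.74, the 1 of 6 endodermis, exodermis and root hair genes to change.

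Single hormone and sugar genes rose and fell at day 7. GA20ox1 rose 34.1-fold, to 66.1 ± 15.7 CPM (5.09 ± 0.75, edgeR adjusted p = 0.00117), and LOG (LOC_Os01g40630), a cytokinin-activating enzyme, rose 12.5-fold (3.64 ± 0.86, edgeR adjusted p = 0.0159). The brassinosteroid receptor gene BRI1 (LOC_Os01g52050) and the brassinosteroid synthesis gene D11 (LOC_Os04g39430) fell 7.62-fold and 7.41-fold, at -2.93 ± 0.69 and -2.89 ± 0.73. SWEET4 rose from 2.31 ± 1.47 to 78.6 ± 76.1 CPM (5.13 ± 0.95, edgeR adjusted p = 0.00426), SWEET12 fell 23.1-fold (-4.53 ± 1.06) and SUS1 fell 1.99-fold (-0.99 ± 0.29). Of the tested members 1 of 7 gibberellin, 1 of 11 auxin and cytokinin, 2 of 5 brassinosteroid and 3 of 15 sugar genes passed over all genes, against 1, 3, 2 and 6 adjusted over the list alone. None of these 4 lists passed with camera (adjusted p = 0.497, 0.947, 0.0751 and 0.298). With fry the brassinosteroid list passed downward and the sugar list upward, each with an adjusted p of 0.0312.

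Defence genes went both ways at day 7. PR1a rose 7.21-fold (2.85 ± 0.80) and PBZ1 (LOC_Os12g36880), a pathogenesis-related gene, 23.5-fold (4.55 ± 1.39), while ICS1 (LOC_Os09g19734), an isochorismate synthase of the salicylate pathway, fell 2.61-fold (-1.38 ± 0.35), with edgeR adjusted p of 0.0316, 0.0479 and 0.0223. Adjusted over the list alone 5 of 10 members passed, with WRKY45 (LOC_Os05g25770), a transcription factor gene of salicylate defence, at -1.13 ± 0.40. The salicylate and pathogenesis-related list did not pass (camera adjusted p = 0.803). Phytoalexin synthesis genes were higher with a median of 2.36 (camera adjusted p = 3.61e-04, but adjusted p = 0.341 with an estimated correlation). Among them KSL7 (LOC_Os02g36140), a diterpene synthase, was at least 15.5-fold higher. The cytochrome P450 gene CYP99A3 (LOC_Os04g09920) rose from 2 to 50 counts (ratio 17.4, interval 4.57 to 148). In all, 2 of 12 members rose over all genes and 5 adjusted over the list alone.

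Iron uptake genes were again lower at day 7, with a median of -1.89 (camera adjusted p = 4.96e-04, but adjusted p = 0.0886 with an estimated correlation). NAS2 (LOC_Os03g19420), a nicotianamine synthase, fell 5.25-fold (-2.39 ± 0.69, edgeR adjusted p = 0.0350), the 1 of 5 over all genes, and 5 of 5 passed adjusted over the list alone. CATA rose 6.57-fold (2.72 ± 0.43, edgeR adjusted p = 0.00164) and APX1 (LOC_Os03g17690), an ascorbate peroxidase, 2.94-fold (1.56 ± 0.38). The nitrate transporter gene NRT2.1 (LOC_Os02g02170) rose 25.8-fold, from 0.671 ± 0.91 to 15.7 ± 21.8 CPM (4.69 ± 1.43). The ammonium transporter gene AMT1-1 (LOC_Os04g43070) fell 8.07-fold, from 94.0 ± 114 to 11.6 ± 7.83 CPM (-3.01 ± 0.75). For NRT2.1 in galls and AMT1-1 in root tips the SD exceeded the mean, and both calls were lost with a single library left out, as given below. The lignin pathway gene 4CL3 (LOC_Os02g08100) rose 4.42-fold (2.14 ± 0.62). Outside the iron list, 2 of 7 oxidative burst, 2 of 6 nitrogen and 1 of 10 secondary wall genes passed over all genes, against 3, 2 and 1 adjusted over the list alone, and no list of these passed with camera (adjusted p = 0.257, 0.803 and 0.796). With fry the oxidative burst list passed upward (adjusted p = 0.0355). The jasmonate, ethylene, primary wall cellulose, stem cell niche and endodermis lists did not pass either (camera adjusted p from 0.497 to 0.947). Of 5 ethylene genes 1 was higher and 1 lower adjusted over the list alone, and of 7 jasmonate genes 1 was higher. In all, 6 lists passed with fry and 4 with camera at day 7, the phytoalexin list with camera alone.

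At day 7 1938 features differed between galls and root tips, 1092 higher and 846 lower. Over all 23927 features, called or not, the libraries separated completely in 6487, where chance gives 10%. The genes called at both days numbered 46 higher in both, 40 lower in both and 3 in opposite directions, where independent lists would share 6.57 and 4.74. Outside the lists and chosen after their values were seen, LOC_Os01g66010 rose from 0.435 ± 0.379 to 232 ± 89.3 CPM (8.78 ± 1.39), and LOC_Os06g31890 fell from 92.0 ± 57.8 to 1.02 ± 1.03 CPM (-6.28 ± 1.14). GA20ox1, SWEET4, CATA, PSBO, CAB2R, LHCA1, LHCA4 and LHCB6 kept an adjusted p under 0.05 whichever of the 6 libraries was left out, and the other 24 list genes called did not. When the fit held the 6 libraries alone, 15 of the 32 list genes missed the threshold (adjusted p from 0.0504 to 0.147), and 10 of the 32 kept it under every alternative that left out no single library. Mock root tip replicates 1, 2 and 3, left out in turn, ended 16, 19 and 16 of these calls, and gall replicates 1, 2 and 3 ended 12, 18 and 12, among them BRI1 at 0.264 and AMT1-1 at 0.213 without mock root tip replicate 1 and NRT2.1 at 0.304 without gall replicate 3. The number of genes was 759 and 1261 without gall replicates 2 and 3, 1119, 822 and 1084 without mock root tip replicates 1, 2 and 3, and 371 when the fit held the 6 libraries alone. DESeq2 called more, as given with the processing.

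**Figure D2:**
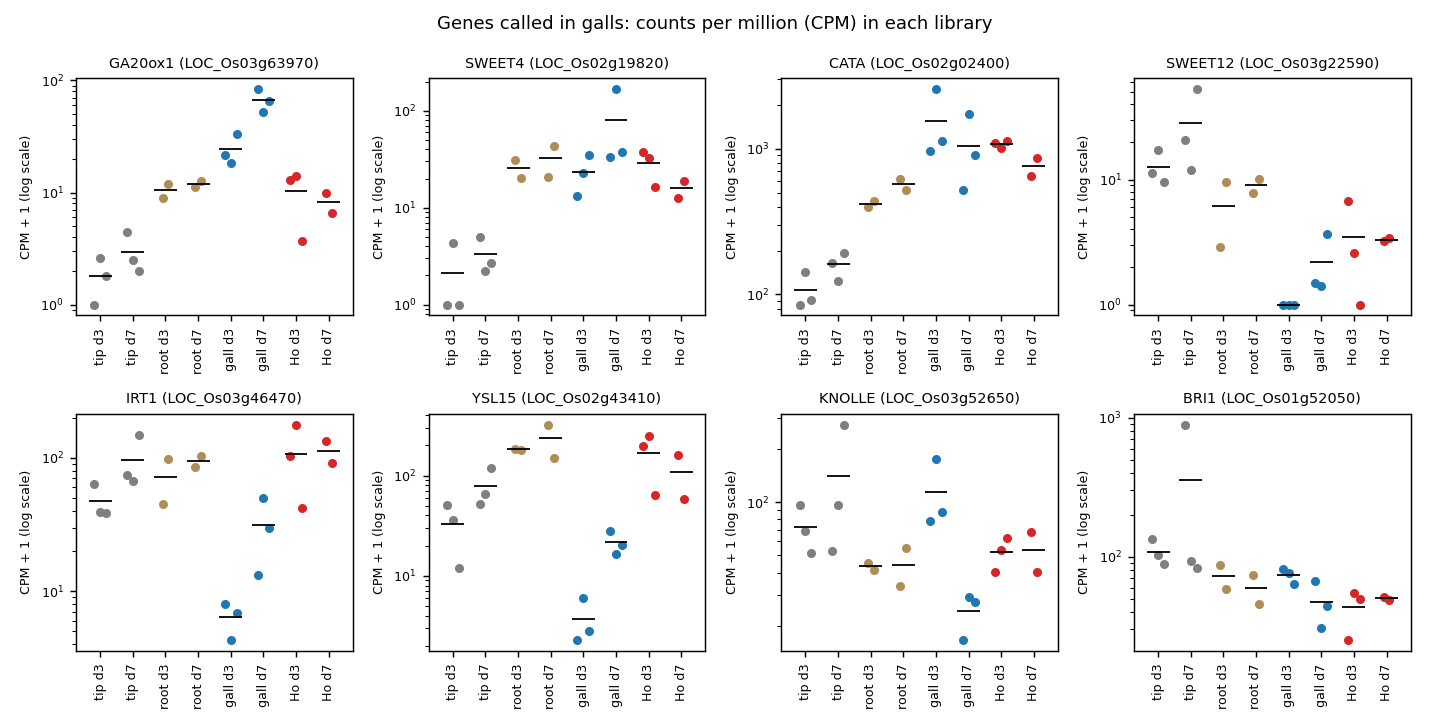
CPM plus 1 on a log scale for 8 genes in each library (points) with the group mean (line), by mock root tip (dark grey), mock root (brown), Meloidogyne gall (blue) and Hirschmanniella root (red, Ho) at days 3 and 7 (d3, d7). GA20ox1, SWEET4 and CATA lie higher in all gall libraries than in all root tip libraries of the same day, and SWEET12, IRT1 and YSL15 lie lower.

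The change of the gall response between days was tested to ask whether young and older galls differ. LHCB6 went from a log2 fold change of -0.57 in day 3 galls to 5.51 in day 7 galls. This difference was 6.08 ± 1.26 SE (edgeR adjusted p = 0.0363). LHCB6 was the 1 of 25 photosynthesis genes past the threshold, with 4 adjusted over the list alone. Galls went from 1.19 ± 1.04 to 12.8 ± 3.54 CPM. Root tips went from 1.73 ± 0.416 to 0.203 ± 0.352 CPM, below the floor, so part of the difference lies in the tips and its size is uncertain. SUS1 was higher in galls at day 3 (1.12) and lower at day 7 (-0.99), a difference of -2.11 ± 0.41 (edgeR adjusted p = 0.0340). Dividing cell genes had a median difference of -2.77, with 0 of 6 over all genes and 4 adjusted over the list alone (camera adjusted p = 6.91e-05 and fry adjusted p = 0.00293, but adjusted p = 0.0513 with an estimated correlation). KNOLLE, named after its value was seen, stood at -3.27 ± 0.78 with an edgeR adjusted p of 0.0529. The photosynthesis list passed with camera (adjusted p = 0.0254), but not with an estimated correlation (camera adjusted p = 0.630). Its median difference of 1.32 is the value of a gene at 0 CPM in both day 3 groups. That median is thus set by the fit and gives no size of the change. The other 15 lists did not pass (camera adjusted p from 0.0655 to 0.833). In all 120 features differed in their response between days, 66 with a more positive change at day 7 and 54 with a more negative one. With RLE size factors 60 were more positive and 24 more negative, a share of 71.4% in place of 55%. LHCB6 missed the threshold without mock root tip day 3 replicates 2 and 3 (0.0679 and 0.0665), mock root tip day 7 replicates 1, 2 and 3 (0.0551, 0.0561 and 0.0628), gall day 3 replicates 3 and 5 (0.0507 and 0.0557) or gall day 7 replicate 2 (0.0517). SUS1 missed it without the same libraries except mock root tip day 7 replicate 1 and gall day 3 replicate 5 (0.0542 to 0.0615). The number was 29 and 19 without mock root tip day 3 replicates 2 and 3, 71, 8 and 54 without mock root tip day 7 replicates 1, 2 and 3, 50 and 11 without gall day 3 replicates 3 and 5, 21 without gall day 7 replicate 2, and 3 when the fit held only galls and root tips. It was 180 without gall day 3 replicate 1. DESeq2, a fit without a filter and the stricter filter also called more, as given with the processing.

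Infected and mock roots were compared to ask how the root responds to a migratory nematode. Roots invaded by Hirschmanniella carried less transcript of photosynthesis genes and more of salicylate and pathogenesis-related defence genes than mock roots at day 3, as lists. LHCB5 (LOC_Os11g13890), a minor light-harvesting protein gene, stood at 265 ± 199 CPM in mock roots (n = 2) and 30.6 ± 4.23 in infected roots (n = 3), a log2 difference of -3.11 ± 0.62 SE (edgeR adjusted p = 0.0919). All 25 photosynthesis genes had a negative fold change, with a median of -2.29 (camera adjusted p = 1.45e-17, and adjusted p = 0.00620 with an estimated correlation). Salicylate and pathogenesis-related genes had a median of 1.97 and 8 of 10 members above 0 (camera adjusted p = 4.29e-05, and adjusted p = 0.0391 with an estimated correlation). The 2 members below 0 were NH1 (LOC_Os01g09800), at 59.9 ± 3.41 CPM in mock roots and 37.4 ± 1.4 in infected roots, and ICS1, at 208 ± 57.7 and 201 ± 7.82. The diterpenoid and flavonoid phytoalexin genes had a median of 3.41 and 12 of 12 members above 0 (camera adjusted p = 1.02e-10, but adjusted p = 0.0784 with an estimated correlation).

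The members behind these list results were named after their values were seen, since no gene passed singly by edgeR. PR1a stood at 10.7 ± 0.566 CPM in mock roots and 263 ± 132 in infected roots (4.61 ± 1.01), WRKY45 at 80.0 ± 15.4 and 317 ± 61.8 (1.99 ± 0.47), and the phenylalanine ammonia-lyase gene LOC_Os05g35290 at 37.0 ± 15.6 and 244 ± 152 (2.72 ± 0.76), with edgeR adjusted p of 0.0919, 0.110 and 0.145. In the phytoalexin list the momilactone gene CYP99A3 stood at 3.89 ± 1.03, the cytochrome P450 genes CYP76M8 (LOC_Os02g36070) and CYP71Z7 (LOC_Os02g36190) at 3.87 ± 1.12 and 5.29 ± 1.67, and KSL8 (LOC_Os11g28530), a diterpene synthase, at 3.00 ± 1.04. AOS2 (LOC_Os03g12500), an allene oxide synthase of jasmonate synthesis, stood at 3.55 ± 1.18, and RR10 (LOC_Os12g04500), a cytokinin response regulator, at -2.52 ± 0.73. Adjusted over the list alone, 11 of 25 photosynthesis, 7 of 12 phytoalexin, 3 of 10 salicylate, 1 of 7 jasmonate, 1 of 6 nitrogen, 1 of 6 dividing cell and 1 of 11 auxin and cytokinin genes passed, against 0 over all genes in each. Secondary wall and jasmonate lists had medians of 0.90 and 1.19, each with a camera adjusted p of 0.00486, but adjusted p = 0.324 and 0.111 with an estimated correlation. The other 12 lists did not pass (camera adjusted p from 0.0675 to 0.840). With fry 4 lists passed, the same as with camera except the secondary wall list.

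For single features, edgeR called 0 of 23927 at day 3 (3031 at an unadjusted p under 0.05, smallest adjusted p 0.0919), while DESeq2 called 665, 388 higher and 277 lower. Without mock root replicate 1 edgeR called 126, with the lone mock library assumed to vary like the other groups. Without infected root replicates 1 or 3 it called 1 each.

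At day 7 photosynthesis genes were again lower as a list in infected roots than in mock roots. CAB2R stood at 555 ± 275 CPM in mock roots and was 22.2-fold lower in infected roots (n = 2 and 2), a log2 difference of -4.47 ± 1.00 SE (edgeR adjusted p = 0.273), and LHCB6 at 320 ± 204 and 20.3 ± 6.99 (-3.98 ± 0.83, edgeR adjusted p = 0.273). The list had a median of -3.06, 24 of 25 members below 0 and 22 with both infected libraries below both mock libraries (camera adjusted p = 3.25e-35, and adjusted p = 1.82e-04 with an estimated correlation). The salicylate list had a median of -0.11 and the phytoalexin list of -0.29 and neither passed (camera adjusted p = 0.960 and 0.910), with 2 libraries in each group. Most genes of these lists had higher means in mock roots of day 7 than of day 3, as given with the change between days. Of the photosynthesis genes 15 passed adjusted over the list alone, against 0 over all genes.

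Further members were again named after their values were seen. LHCB5 stood at -3.27 ± 0.73, LHCA1 at -4.44 ± 0.99 and RBCS2 (LOC_Os12g17600), a small subunit of Rubisco, at -6.08 ± 1.41, from 141 ± 151 CPM in mock roots to 2.09 ± 2.27. The cytokinin response regulators RR9 (LOC_Os11g04720) and RR10 stood at -3.76 ± 1.15 and -2.76 ± 0.85, and the root patterning gene SCR1 (LOC_Os11g03110) at 2.25 ± 0.80. Auxin and cytokinin genes had a median of -1.11 (camera adjusted p = 0.00803, but adjusted p = 0.216 with an estimated correlation), with 2 of 11 adjusted over the list alone. Nitrogen genes had a median of -1.15 (camera adjusted p = 0.0431, but adjusted p = 0.311 with an estimated correlation). 1 member each of the stem cell niche and primary wall lists passed adjusted over the list alone, and the other 14 lists did not pass (camera adjusted p from 0.0578 to 0.975). With fry 1 list passed, photosynthesis.

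For single features, edgeR called 0 of 23927 at day 7 (1393 at an unadjusted p under 0.05, smallest adjusted p 0.273), while DESeq2 called 193, 72 higher and 121 lower. Without mock root replicate 2 edgeR called 64, and without infected root replicate 1 it called 30, with a lone library in the group assumed to vary like the other groups.

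**Figure D3:**
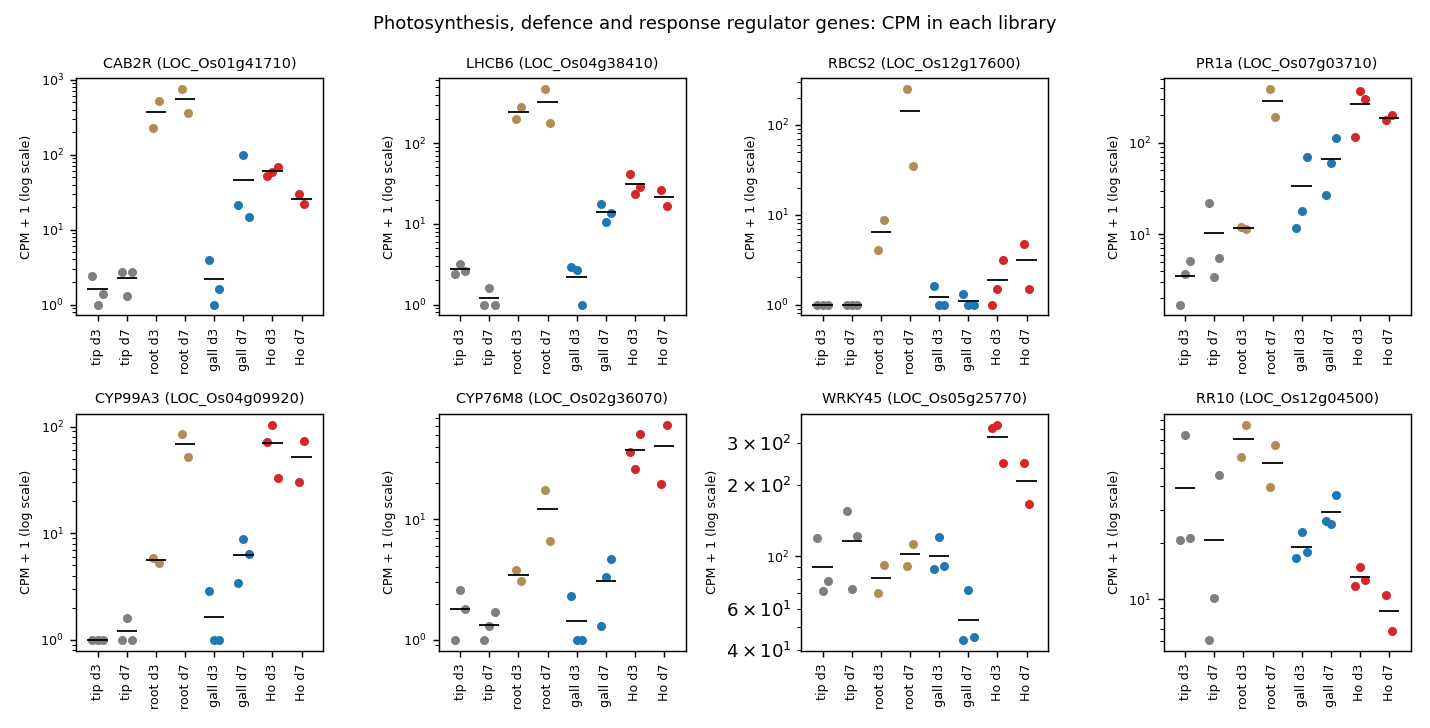
CPM plus 1 on a log scale for 8 genes in each library (points) with the group mean (line), coloured as mock root tip (dark grey), mock root (brown), Meloidogyne gall (blue) and Hirschmanniella root (red, Ho) at days 3 and 7 (d3, d7). CAB2R and LHCB6 lie higher in all mock root libraries than in all Hirschmanniella root libraries, and PR1a rises in mock roots from a mean of 10.7 CPM at day 3 to 289 at day 7.

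The change of the Hirschmanniella response between days was tested to ask whether early and later responses differ, and no list passed with an estimated correlation or with fry. PR1a stood at 10.7 ± 0.566 and 289 ± 139 CPM in mock roots at days 3 and 7, and at 263 ± 132 and 188 ± 15.2 in infected roots. CYP99A3 stood at 4.57 ± 0.421 and 67.3 ± 22.6 in mock roots and at 68.4 ± 35.6 and 50.3 ± 30.3 in infected roots. All tested phytoalexin genes, and all tested salicylate genes but NH1, had a higher mean in mock roots at day 7 than at day 3. In infected roots the means of both lists went both ways. A smaller difference at day 7 is thus no measure of a fading response in infected roots. The phytoalexin list had a median difference of -3.94 between the day 7 and day 3 responses (camera adjusted p = 2.94e-07, but adjusted p = 0.195 with an estimated correlation), secondary wall genes of -1.35 (8.65e-04), salicylate genes of -1.20 (0.00177), nitrogen genes of -2.01 (0.00690), jasmonate genes of a mean of -1.54 (0.0179) and iron genes of -1.27 (0.0295). Dividing cell genes had a median difference of 1.22 and photosynthesis genes of -0.77 (both 0.0295). The adjusted p with an estimated correlation was 0.357 for photosynthesis, 0.209 for iron and 0.195 for each of the other 6 lists, and the other 9 lists did not pass (camera adjusted p from 0.0793 to 0.642). Adjusted over the list alone, 3 phytoalexin, 2 secondary wall and 1 each of the salicylate, nitrogen, jasmonate, dividing cell and stem cell niche genes passed, against 0 over all genes. For single features edgeR called 0 (2000 at an unadjusted p under 0.05), and DESeq2 called 105. By edgeR 5 were called without mock root day 3 replicate 1, 6 without mock root day 7 replicate 2, 1 without infected root day 3 replicate 1 and 3 without infected root day 7 replicate 1, with any lone library in a group assumed to vary like the other groups.

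The responses to both nematodes were set against each other to ask where they differ. At day 7 photosynthesis genes were higher in galls and lower in Hirschmanniella roots as lists, and the difference of log2 fold changes was 9.64 ± 1.40 SE for CAB2R, 9.49 for LHCB6, 8.80 ± 1.38 for LHCA4 and 12.61 ± 1.76 for LHCA1, where the last includes a group at 0 counts and is no bound (edgeR adjusted p = 0.00483, 0.00170, 0.00820 and 0.00536). LHCB6 and LHCA4 each stood at 0.203 CPM in root tips of day 7, below the floor, so their sizes are uncertain. Of the photosynthesis list 10 of 25 differed over all genes and 19 adjusted over the list alone. Its median was 6.12 (camera adjusted p = 4.66e-29, and adjusted p = 4.58e-04 with an estimated correlation). GA20ox1 and SWEET4 also responded more in galls, by 5.69 ± 1.08 and 6.21 ± 1.36 (edgeR adjusted p = 0.0175 and 0.0374). Dividing cell genes differed by a median of -2.60, with 0 of 6 over all genes and 5 adjusted over the list alone (camera adjusted p = 7.05e-05, and adjusted p = 0.0327 with an estimated correlation). Phytoalexin genes differed by a median of 3.74 (camera adjusted p = 0.00254, but adjusted p = 0.465 with an estimated correlation), and the other 14 lists did not pass (camera adjusted p from 0.0573 to 0.848). With fry 2 lists passed, photosynthesis and dividing cells. In all 194 features differed at day 7, 119 with a more positive response in galls and 75 with a more negative one. Without Hirschmanniella root replicate 2 the adjusted p of these 6 genes ran from 0.0962 to 0.195. Without mock root replicate 1 or Hirschmanniella root replicate 1 GA20ox1 (0.0850 and 0.0751), LHCA4 (0.0525 and 0.0523) and SWEET4 (0.0958 and 0.189) did not pass. SWEET4 also did not pass without mock root replicate 2 (0.0781), gall replicate 2 (0.0734) or mock root tip replicates 2 and 3 (0.0738 and 0.0679). This comparison joins nematode and tissue, and the number dropped to 2 without Hirschmanniella root replicate 2, to 6 without mock root replicate 1, to 52 without Hirschmanniella root replicate 1, to 78 and 121 without mock root tip replicates 2 and 3, and to 88 without gall replicate 2. A lone library left in a root group is assumed to vary like the other groups. With RLE size factors the median over all genes was 0.167, against 0.0506 with TMM factors. DESeq2 and a fit without a filter called more features than the 194, as given with the processing.

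At day 3 11 features differed between the responses, 6 more positive in galls and 5 more negative, and 0 of them were list members. Photosynthesis genes had a median difference of 2.41 and iron genes of -3.48 (both with a camera adjusted p of 1.55e-04, but adjusted p = 0.178 and 0.0762 with an estimated correlation). Secondary wall genes had a median difference of -1.43, oxidative burst genes of 1.92 (both 0.00155), salicylate genes a mean of -1.02 (0.0326) and nitrogen genes a median of -2.90 (0.0398). The adjusted p with an estimated correlation was 0.0762 for oxidative burst and 0.192 for each of the other 3. The other 11 lists did not pass (camera adjusted p from 0.0659 to 0.880). With fry 5 lists passed, photosynthesis, iron, oxidative burst, sugar and ethylene. Adjusted over the list alone, 4 photosynthesis, 4 iron, 2 oxidative burst, 2 salicylate and 1 nitrogen genes passed, as did 3 endodermis, 3 sugar and 1 each of the ethylene, auxin and cytokinin and gibberellin genes, against 0 over all genes. The number of features was 32, 3 and 24 without gall replicates 1, 3 and 5, 5 without mock root tip replicate 2, 31 and 4 without mock root replicates 1 and 2, and 19 without Hirschmanniella root replicate 3, with a lone mock root library assumed to vary like the other groups.

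Mock root tips and mock roots, the control tissues, differed in many of these genes. CAB2R stood 541-fold lower in root tips than in roots over both days (-9.08 ± 0.77 SE, edgeR adjusted p = 5.87e-07, n = 6 and 4), and 22 of 25 photosynthesis genes were lower over all genes and adjusted over the list alone (median -6.80, camera adjusted p = 2.33e-50, and adjusted p = 3.30e-05 with an estimated correlation). Root tips also held less PR1a (-3.51 ± 0.63), CYP99A3 (-7.37 ± 0.98), SWEET4 (-4.15 ± 0.70), GA20ox1 (-2.95 ± 0.56), LOG (-3.90 ± 0.66), CATA (-1.91 ± 0.32), 4CL3 (-3.01 ± 0.48) and YSL15 (-2.06 ± 0.47), with edgeR adjusted p from 7.26e-05 to 0.00631, that of YSL15 being 0.0516 without mock root day 7 replicate 1. Genes that rose in galls against root tips, such as SWEET4, GA20ox1, LOG, CATA, PR1a and 4CL3, thus also stood higher in mock roots than in mock root tips. At day 7 mean CPM in galls lay above that in mock roots for GA20ox1 (66.1 ± 15.7 against 10.9 ± 1.16), CATA (1050 ± 616 against 572 ± 69.2) and SWEET4 (78.5 ± 76.1 against 31.3 ± 16.2). It lay below for LOG (19.9 ± 11.5 against 33.4 ± 25.1), PR1a (65.3 ± 42.9 against 289 ± 139) and 4CL3 (131 ± 53.6 against 474 ± 267). Galls were not tested against mock roots. CYP99A3 stood at 0 CPM in root tips of day 3 and 0.203 ± 0.352 at day 7, so its -7.37 is no measured fold. LHCA3 and LHCA4 of the photosynthesis list and CYP71Z7 of the phytoalexin list also stood at 0 CPM in day 3 root tips. The medians of both lists rest in part on such fitted values.

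Of the 148 list members tested, 57 were lower in root tips and 0 higher. Phytoalexin genes were lower in 9 of 12 cases (median -5.61, camera adjusted p = 2.22e-11), secondary wall genes in 4 of 10 (-1.10, 1.38e-04), salicylate genes in 5 of 10 (-1.21, 1.80e-04), jasmonate genes in 1 of 7 (-1.08, 0.0197) and auxin and cytokinin genes in 3 of 11 (-1.13, 0.0349). In the same order, adjusted p = 0.0943, 0.154, 0.0594, 0.154 and 0.190 with an estimated correlation. Adjusted over the list alone these counts were 12, 5, 5, 2 and 5. Dividing cell genes were higher in root tips by a median of 1.01, with 0 of 6 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0279, but adjusted p = 0.176 with an estimated correlation). Both homeobox genes of the KNOX class tested, OSH15 (LOC_Os07g03770) at -3.98 ± 1.02 (adjusted p 0.0868 and 0.0980 without mock root day 3 replicate 1 and day 7 replicate 1) and OSH71 (LOC_Os05g03884) at -2.03 ± 0.40, were lower in root tips over all genes and adjusted over the list alone. OSH15 stood near 0 in root tips, at 0.136 ± 0.235 and 0.116 ± 0.200 CPM at days 3 and 7, so its size is uncertain. The other 10 lists did not pass with camera (adjusted p from 0.157 to 0.884). With fry 11 lists passed, the 7 that passed with camera and the sugar, nitrogen, gibberellin and oxidative burst lists. In all 2836 features differed, 776 higher and 2060 lower in root tips, and leaving out mock root day 3 replicates 1 or 2, or day 7 replicates 1 or 2, gave 1808, 1504, 1438 and 1887, with the lone library of that day assumed to vary like the other groups.

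**Figure D4:**
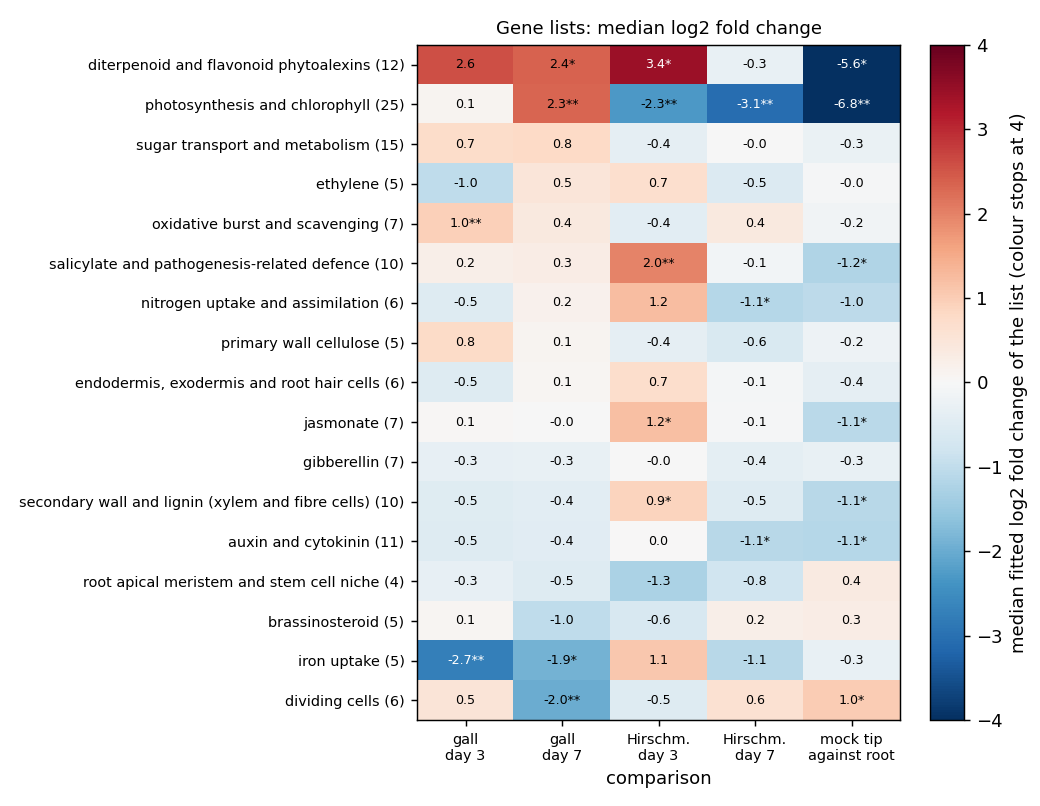
Median fitted log2 fold change of each gene list (lines, with the number of tested members in brackets) in 5 comparisons (columns), where 1 star marks a camera adjusted p under 0.05 and 2 stars mark that the adjusted p with an estimated correlation was also under 0.05. Colours stop at 4 on the log2 scale, and the photosynthesis list goes from 2.33 in day 7 galls to -3.06 in day 7 Hirschmanniella roots and -6.80 in mock root tips against mock roots.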

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

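The tests of whether the 2 loci with the highest counts made the gall calls, of whether infection changed those loci and of RNA from another organ were chosen only after the result was seen. The response of 120 features to Meloidogyne differed between days by a test of the difference itself, among them LHCB6 at 6.08 and SUS1 at -2.11 on the log2 scale. Between the Meloidogyne and Hirschmanniella responses 11 features differed at day 3 and 194 at day 7. At day 7 those differences were 5.69 for GA20ox1, 9.64 for CAB2R, 9.49 for LHCB6, 12.61 for LHCA1, 8.80 for LHCA4 and 6.21 for SWEET4, where that of LHCA1 includes a group at 0 counts and is no bound. In root tips of day 7 LHCB6 and LHCA4 lay below the floor, so the sizes given for them are uncertain.

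Photosynthesis genes were lower in Hirschmanniella roots than in mock roots at both days, with medians of -2.29 and -3.06. Scaling or the dominant loci did not account for it, since the highest day 7 median over 4 other settings was -3.06. RNA from another organ mixed in 1 fixed ratio into the mock root libraries cannot be told apart from a change in the roots. The members' median biological coefficient of variation between mock root libraries of both days, scaled to the list total, was 0.315. Matched gene sets, scaled by library size instead, gave 0.397 and a 95th percentile of 0.520. Scaling to the list total removes variation that members share. The values are thus not measured alike, and the test could hardly have excluded this source. An effect of infection on greening of the root stays open and was not tested.

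More genes were called in galls at day 7 (1938) than at day 3 (278). Deeper libraries did not account for it, since thinning the day 7 libraries to the day 3 depths left at least 1806 in 10 thinnings. A larger spread at day 3 did not either, since the common biological coefficient of variation was 0.648 at day 3 and 0.677 at day 7, a ratio of 0.956. The difference of stage stays open, and a larger response of older galls is a hypothesis found and tested on the same libraries.

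LOC_Os09g01000 and LOC_Os09g00999 took up to 65.7% of a library's counts. Their counts as such did not make the day 7 gall calls, since 1939 features were called at day 7 without them. Leaving them out cannot test what goes with a high share, such as fewer counts at other features. Features with mitochondrial locus names also stood higher in libraries with a high share. In day 3 root tips they summed to 696 CPM in replicate 1 (share 65.7%) and 22.4 in replicate 3 (0.950%). High-share and low-share libraries overlapped in this, with 136.5 CPM in mock root tip day 7 replicate 1 (1.61%) and 127 in mock root day 3 replicate 1 (22.9%). With their share as a covariate day 3 galls gave 171 features in place of 278, and the change in galls 59 in place of 120. The day 7 difference between responses gave 105 in place of 194. In day 7 galls 7 of the list genes called then missed the threshold (edgeR adjusted p from 0.0530 to 0.0737). The cause of these drops was not tested. Whether infection changed the level of these loci cannot be told from these libraries. The mean difference of log2 percent, infected minus mock, was 0.327. The mean percent was 13.3 in infected and 21.2 in mock libraries, the other way. For the log2 value the two-sided exact permutation p was 0.757 within tissue and day, over all 24000 arrangements. What the loci encode is not given in the sources used here.

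For galls against root tips 1 of the 10 splits of the 6 libraries, the real one, gave as many features at day 3 (278, highest other 0) and at day 7 (1938, highest other 7), and 10 splits are too few for a share under 0.05. For the change of the Meloidogyne response between days 5 of 100 splits gave at least the real 120, which by the rule set beforehand does not exclude chance. The highest other, 1590, is the split that exchanges galls and tips at day 7 alone and so adds the responses of both days. All 5 keep the day 7 galls and root tips whole and so hold the day 7 response. For mock root tips against mock roots 1 of 100 splits, the real one, gave as many as 2836 (highest other 939). This is the smallest share possible and lies under the 0.05 of the rule set beforehand, which makes chance unlikely without excluding it.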

How the results depend on the processing

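Fits without the 2 dominant loci, with their share as a covariate and without day 3 galls were chosen only after the result was seen. With RLE or upper-quartile factors, or without those loci, the total number of genes in every comparison stayed within 1.5 times of its reported value. Without a filter the counts were 1623 for galls at day 3, 770 and 298 for Hirschmanniella roots at days 3 and 7, 1416 and 317 for the change of the Meloidogyne and Hirschmanniella responses between days, and 944 and 1148 for the difference between responses at days 3 and 7. DESeq2 gave 1203 and 3348 for galls, 665 and 193 for Hirschmanniella roots, 1372 and 105 for the changes between days, and 660 and 1097 for the differences between responses. The stricter filter gave 239 for the change in galls. Fits on libraries of the same tissue gave 34 and 953 for galls, 3 for Hirschmanniella roots at day 3, and 3 and 3 for the changes between days. Fits on the groups compared gave 0 and 371 for galls, 3 and 3 for the changes between days, and 0 and 30 for the differences between responses; fewer libraries then carry the spread. With the replicate number as a block, day 7 galls gave 1192 and the day 7 difference between responses 100, against 2039 and 166 in the same libraries without it. No paired analysis was possible for comparisons with day 3 galls because their replicate numbers differ between the labels and the deposited table. With the share as a covariate day 3 galls gave 171, the change in galls 59 and the day 7 difference between responses 105. Except where stated, the cause was not tested.

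Leaving out 1 library gave 80 to 364 for galls at day 3 and 759 to 1388 at day 7, 0 to 126 and 0 to 64 for Hirschmanniella roots, 8 to 180 and 0 to 6 for the changes between days, 3 to 32 and 2 to 175 for the differences between responses, and 1438 to 2830 for root tips against roots. List tests kept the call in 157 tests under other settings and lost it in 33, most of them with an estimated correlation. The replicate block ended it for photosynthesis in the change of the Hirschmanniella response and for dividing cells between control tissues, and the share as a covariate for nitrogen in the day 3 difference between responses. Among named genes, 1 changed direction: CATC (LOC_Os03g03910) in day 7 galls, at -3.97 (edgeR adjusted p = 0.0907), ranged from -4.85 to 1.06 with 1 library left out, the latter without mock root tip day 7 replicate 3, the cause being 1 library with most of its counts.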

Other observations

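The counts of unannotated regions, the shares with the same sign and the correlations were chosen only after the result was seen. Unannotated transcribed regions also differed between galls and root tips, 10 higher and 10 lower at day 3 and 101 higher and 60 lower at day 7, of 2480 tested. Of the 1938 features called in day 7 galls, 1228 (63.4%) had the same sign in day 3 galls and 859 (44.3%) in day 7 Hirschmanniella roots. Of the 278 called in day 3 galls, 150 (54%) had the same sign in day 3 Hirschmanniella roots. Across all genes, which are not independent replicates, the log2 fold changes in galls at days 3 and 7 had r = 0.193, and those in galls and Hirschmanniella roots at day 7 had r = -0.053.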
